A study of Mus musculus with 38 samples.

How the data were processed

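The design text describes total RNA of embryonic fibroblasts (12.5 days post coitum) and thymus (18.5 days post coitum) that was amplified, labelled with Cy3 or Cy5 and hybridised on 2-colour arrays against a wild-type pool of the same tissue, with dye swaps. Of the thymus arrays, 2 were excluded by the submitters for quality, per the design text. The arrays were read on an Agilent G2565AA scanner. Feature extraction, background correction and normalization are not given in the sources used here. The deposited table holds 1 log2 ratio per spot and array for 25344 spots and 38 arrays. Scanner intensities were not used here, so background correction, loess normalization, a filter on dim probes and slide or scan batches could not be tried, and signal over background is unknown.

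Scale, centring and direction of the deposited log2 ratios were read from the values. The values are bounded at 16.61 on the log2 scale. The upper bound was reached 445 times on the 19 arrays with the hypomorph in Cy5 and never on the other 19, and the lower bound 423 times on the arrays with it in Cy3 only. This fits ratios of hypomorph over pool whose sign the submitters had already turned on the Cy3 arrays. In the embryos where Eif2s3y lay furthest from the pool (thymus embryos 1 and 2, fibroblast embryos 1, 2, 3 and 5) it had the same sign in both orientations, except on array 2 of fibroblast embryo 1. In thymus embryo 5 and fibroblast embryo 4 the orientations differed in sign. The decreases were deeper than the increases, which points to hypomorph over pool if the pools hold both sexes. The labels do not state the sexes. The array medians were not at 0 (-0.887 to 1.14), so the table had not been normalized. Arrays of 1 embryo in opposite orientations correlated between -0.723 and 0.367 across probes, because a dye profile common to the arrays turns sign with the orientation. A rule fixed before the data were examined read a negative correlation as a sign not yet turned, and it conflicted here with the sex-linked genes and the bounds. The latter were followed. After removal of the dye profile 35 of 38 arrays correlated above 0, on average, with the other arrays of their embryo (-0.200 to 0.658 over all). The 3 below 0 are the doubted fibroblast arrays, and 16 of 38 arrays correlated better with the best matching other embryo than with their own, so these correlations do not settle the direction. Arrays of the same orientation in a tissue all correlated positively, the lowest at 0.221.

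Values at a bound were treated as missing. Each array was centred on its median. The plan had been to use the values as deposited with centring as the alternative. These roles were exchanged when the table proved not to be normalized and before any test was run, and the uncentred values became an added alternative. The value of an embryo is the mean of its mean over arrays with the hypomorph in Cy5 and its mean over arrays with it in Cy3, so that dye effects cancel. The embryo is the replicate, and its arrays are technical repeats. Gene symbols came from the platform annotation paired with the probes: 21111 probes had 1 symbol, none had several and 4233 had none. Of the symbols, 17069 were current in the RefSeq gene table (GRCm38.p6), 3974 were updated through it and 68 were kept. Probes of 1 symbol were averaged (Actb and Gapdh had 257 each), and probes without a symbol stayed in the tests unnamed. A feature needed a value in all 5 embryos, which left 21947 features (18172 of them genes) in thymus and 22025 (18258) in fibroblasts.

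Tests were made in R 4.3.3 with limma 3.58.1. The ratio of each tissue was tested against 0 over its 5 embryos, and thymus minus fibroblasts over all 10, with lmFit and eBayes, two-sided, and Benjamini-Hochberg adjusted p under 0.05. The pool counts as 1 control sample and its own spread is not in the test. Genes were named by a rule fixed before the data were examined. Per tissue it takes the 12 largest rises and the 12 largest falls among genes that passed with the same sign in all 5 embryos. Where fewer than 6 passed in a direction, it takes the largest with an unadjusted p under 0.01, given as not passing. To these it adds up to 4 members per list that passed adjusted over the list alone, the DNA methyltransferases, the study's germ cell genes, and the 8 largest on each side for the difference. In thymus 6 named genes passed as higher, so no others were added on that side.

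Gene lists were also fixed before the data were examined. They were 27 tested lists: germ cell genes recalled from the study's paper, other germ cell and meiosis genes, the Rhox cluster, imprinted genes, DNA methylation machinery, E2F6 and its Polycomb complex, thymocyte, thymic epithelium, MHC class II, fibroblast and matrix, smooth muscle, skeletal muscle, adipose, endothelial, erythroid, myeloid, B and natural killer cell, neural, cartilage and bone, HOX, cell cycle, p53 targets, interferon-stimulated, immediate early, hypoxia and glycolysis, cholesterol synthesis and ribosomal protein genes. Another list of sex-linked genes served only the check of direction. Shifts were tested with camera at a preset correlation of 0.01 for lists with at least 5 measured members, adjusted over the lists of a tissue. Alternatives were camera with an estimated correlation, and fry, which tests whether a set's genes move, on balance, one way and does not compare them with other genes. Of the lists called with the preset correlation none was called with an estimated one (smallest adjusted p 0.193 in thymus and 0.812 in fibroblasts), and fry called 3 in thymus and none in fibroblasts.

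The tests were tried on simulated data whose spreads were drawn from a distribution fitted to the real embryos. Of genes changed by 0.5, 1 and 2 on the log2 scale, 77.6%, 94.0% and 100% were called in thymus among 21947 features, with 9 false calls over all sizes. In fibroblasts these were 64.2%, 88.1% and 98.5% with 11 false calls, and for the difference 57.1%, 89.2% and 100% with 32. A list shifted by 0.3 was called in both tissues and none of 20 unshifted lists was. Simulated genes varied independently and the simulated embryos shared no structure. In the real data the cell cycle genes in fibroblasts, for example, had an estimated correlation of 0.734. The simulation therefore does not check the preset correlation, nor how many changed genes the real tests would call.

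Alternatives fixed in advance were arrays scaled to the same median absolute deviation, 1 dye orientation only, probes tested separately, features with a value in at least 3 embryos, a robust variance prior, embryo weights, a fit of single arrays with a dye term and the embryo as a random block, each embryo left out, thymus arrays without a genotype in the label left out, fibroblast arrays by title prefix, the embryo number as a block for the difference, and lists without members of the sex chromosomes. Chosen after seeing the data were centring of each print block, and the fibroblasts without the 3 doubted arrays or without the 1 that ran opposite. The uncentred values, planned as the main setting, became an alternative when the table proved not to be normalized. All thymus arrays carry the same title prefix. The fit of single arrays took 1 correlation between arrays of an embryo for all features (0.154 in thymus and 0.162 in fibroblasts). For genes that varied more between embryos than this allows, it counts technical repeats in part as replicates.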

Results

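The study set RNA of mouse embryos with hypomorphic Dnmt3b against RNA of wild-type embryos on 2-colour oligonucleotide arrays. Dnmt3b is a de novo DNA methyltransferase, and mutations of its human counterpart underlie ICF syndrome (immunodeficiency, centromeric instability and facial anomalies). Thymus was taken at 18.5 days post coitum from 5 hypomorphic embryos and hybridised on 18 arrays. Mouse embryonic fibroblasts came from 5 hypomorphic embryos at 12.5 days post coitum and were hybridised on 20 arrays. On each array the other channel held a pool of wild-type RNA of the same tissue, made from 5 samples. The embryos were of a hybrid background of 129SvJae and C57BL/6. Every thymus and fibroblast embryo had 4 arrays, 2 for each dye orientation, except thymus embryo 5, which had 1 for each. The labels of the thymus arrays give the genotype m3/m24, except for 3 arrays (1 of embryo 1 and 2 of embryo 3) that give the embryo without it. The fibroblast labels give a number only, and their genotype comes from the design text. Each array had 25344 spots, of which 147 to 423 had no value and 1 to 50 others lay at a bound and were treated as missing. The number of embryos and arrays limits the precision of every value below.

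Dnmt3b itself differed little from the wild-type pools at the single probe that measured it. The mean log2 ratio of hypomorph over pool was -0.08 ± 0.15 (SD, n = 5) in thymus, with values of -0.05, -0.30, 0.13, -0.09 and -0.07 in embryos 1 to 5. In fibroblasts it was 0.11 ± 0.11 (SD, n = 5), with values of 0.00, 0.18, 0.11, -0.01 and 0.25. Neither passed the test (limma adjusted p = 0.917 and 0.359). Where this probe lies relative to the altered part of the gene is not given in the sources used here, so these values do not check the labels. The other DNA methyltransferases stayed near the pools as well. Dnmt1 was at 0.09 ± 0.14 in thymus and -0.01 ± 0.12 in fibroblasts, Dnmt3a at 0.02 ± 0.06 and 0.03 ± 0.08, and Dnmt3l at 0.09 ± 0.49 and 0.01 ± 0.08 (SD, n = 5 each). Of these, Dnmt1 and Dnmt3l in fibroblasts and Dnmt1, Dnmt3a and Dnmt3l in thymus changed sign under at least 1 other processing. In the arrays with the hypomorph in Cy3 alone Dnmt1 in fibroblasts was at 0.18 (limma adjusted p = 0.0361). The dye effect stays in the ratio there, and 8157 features passed in that setting, so this value does not show a rise of Dnmt1.

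Y-linked genes were read on every array to check the direction of the ratios. Eif2s3y, a translation factor gene on the Y chromosome, had mean log2 ratios of -3.43, 0.71, -0.40, 0.27 and -0.40 in thymus embryos 1 to 5, and of -1.35, -2.00, 1.00, 0.66 and -3.69 in fibroblast embryos 1 to 5. Within an embryo the arrays of both dye orientations had the same sign in the embryos with large deviations, except on array 2 of fibroblast embryo 1. Across probes, after removal of the dye profile, 3 fibroblast arrays had a negative mean correlation with the other arrays of their embryo. Of the other arrays, 4 in fibroblasts (arrays 1 and 3 of embryo 1, and 1 and 4 of embryo 2) and 9 in thymus correlated above 0 with their embryo but better with another. On array 2 of fibroblast embryo 1 Eif2s3y was at 0.28, against -2.08 and -2.21 on arrays 1 and 3 of that embryo. Array 4 of the same embryo correlated at r = 0.930 across probes with array 3 of embryo 2, while no other pair of arrays of one dye orientation in a tissue exceeded 0.846. On array 4 of embryo 4 Eif2s3y was at 3.16, against -0.51 to 0.35 on the other 3 arrays of that embryo. On that array several of the most changed genes ran opposite to all 19 other fibroblast arrays. Ifi202b was at 0.76 there and between -6.46 and -0.90 elsewhere, Cd44 at 1.00 against -3.06 to -1.44, Sfrp2 at -2.41 against 0.66 to 3.86, and Slc25a31 at -1.68 against 0.72 to 1.78. The 3 arrays with a negative correlation were kept as labelled, and the fibroblast results are also given without them.

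**Figure D1:**
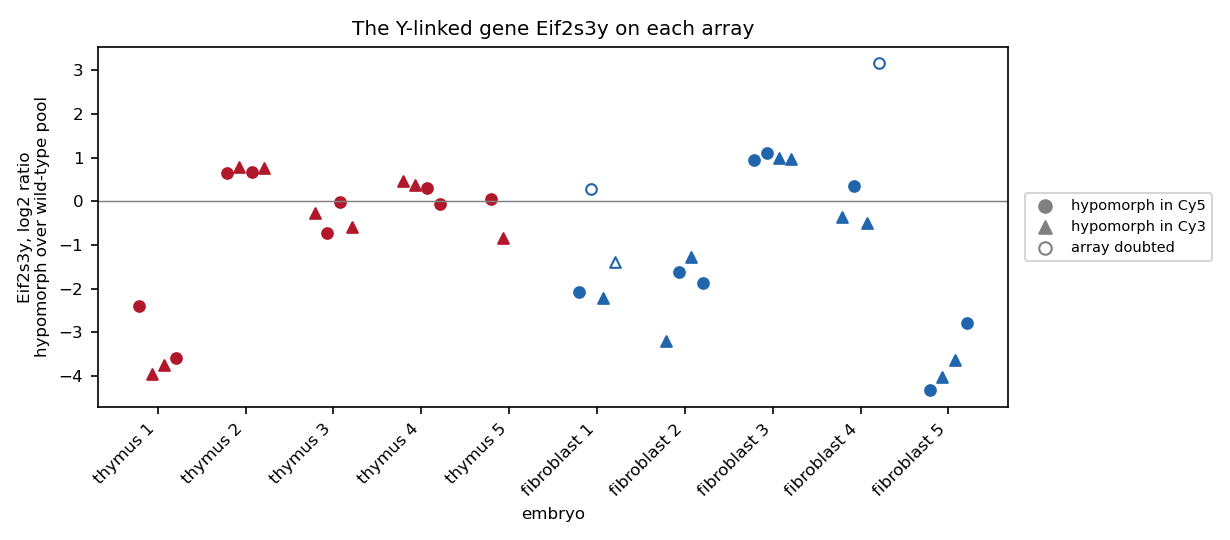
Log2 ratio of the Y-linked gene Eif2s3y, hypomorph over wild-type pool, on each of the 38 arrays, by embryo and dye orientation. Open symbols mark the 3 doubted fibroblast arrays, of which array 4 of embryo 4 lies at 3.16 and array 2 of embryo 1 at 0.28.

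The first comparison asked which genes differ in the thymus of Dnmt3b hypomorphs. Here and below, passing refers to limma on the embryo values of median-centred arrays, unless another processing is named. Rpl39l, a testis-enriched copy of a ribosomal protein gene, rose to 2.36 ± 0.44 on the log2 scale (SD, n = 5; 5.14-fold; limma adjusted p = 0.0123), and Slc25a31, the germ cell ADP/ATP carrier, to 2.23 ± 0.59 (4.69-fold; adjusted p = 0.0493). Gpat2, a glycerol-3-phosphate acyltransferase of the testis, rose to 1.42 ± 0.39 and Taf7l, a germ cell relative of the transcription factor subunit Taf7, to 1.25 ± 0.34 (SD, n = 5; adjusted p = 0.0496 for both). The 2 other named genes rose by less: Myof, a membrane protein of the ferlin family, at 0.68 ± 0.05 (adjusted p = 0.0123), and Pgam2, the muscle phosphoglycerate mutase, at 0.60 ± 0.13 (adjusted p = 0.0496). The 1 named gene that fell was Krt10, a keratin of differentiating epidermis, at -0.49 ± 0.04 (SD, n = 5; adjusted p = 0.0279). All 5 embryos had the same sign for each of these genes.

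In total 8 of 21947 features passed in thymus, 7 higher and 1 lower, the eighth being a higher probe with no gene name. At an unadjusted p under 0.05 there were 1645, where chance alone gives 1097. The largest decreases with the same sign in all 5 embryos that did not pass were H2bu2, a histone H2B gene, at -1.11 ± 0.47 (adjusted p = 0.112), Mbp, myelin basic protein, at -1.02 ± 0.65 (0.285), and Reg3g, an antibacterial lectin, at -0.93 ± 0.54 (0.259; SD, n = 5 each). Fabp1, Grp, Sprr2b, Clec2d, Gadd45gip1, Car3, Adipoq and Ccl27a followed, from -0.88 for Fabp1 to -0.74 for Adipoq and Ccl27a. Clec2d, a ligand of an inhibitory natural killer cell receptor, came closest to passing, at -0.79 ± 0.23 (SD, n = 5; adjusted p = 0.0528). The wild-type pool is 1 control sample, so these tests leave out the spread between wild-type embryos. The count depended on the embryos and on the centring: it was 0 without embryo 1, 3 or 5, 1 without embryo 2, 4 without embryo 4, 1 (higher) in the values as deposited, 4 (3 higher, 1 lower) with each print block centred and 13 (9 higher, 4 lower) with arrays scaled to equal spread. Decreases outnumbered increases with embryo weights (255, 86 higher and 169 lower) and in a fit of single arrays (405, 132 higher and 273 lower).

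Among the germ cell genes recalled from the study's own paper, all 11 measured members lay above the pool in thymus. Over all genes 1 passed, and 7 passed adjusted over the list alone: Slc25a31, Tex11 (1.85 ± 0.56), Syce1 (1.28 ± 0.37), Ddx4 (0.93 ± 0.27), Mael (0.58 ± 0.19), Stag3 (0.33 ± 0.13) and Smc1b (0.25 ± 0.14; SD, n = 5 each). Tex11 and Syce1 act in meiotic chromosome synapsis, Ddx4 is the Vasa helicase of germ cells, Mael acts in piRNA silencing of transposons, and Stag3 and Smc1b are meiotic cohesin subunits. Sycp3 (0.13 ± 0.23), Tuba3b (0.09 ± 0.04), Tuba3a (0.07 ± 0.06) and Tex101 (0.02 ± 0.09) did not pass. As the study chose this list on these samples, its direction is not independent evidence. The list's median was 0.33 (camera adjusted p = 1.29e-15), and adjusted p = 0.193 with an estimated correlation between genes. A separate list of 61 other measured germ cell and meiosis genes was not called (median 0.02, camera adjusted p = 0.204). Of its members, Taf7l and the synaptonemal complex gene Sycp1 (0.53 ± 0.29) passed adjusted over the list alone, both higher.

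**Figure D2:**
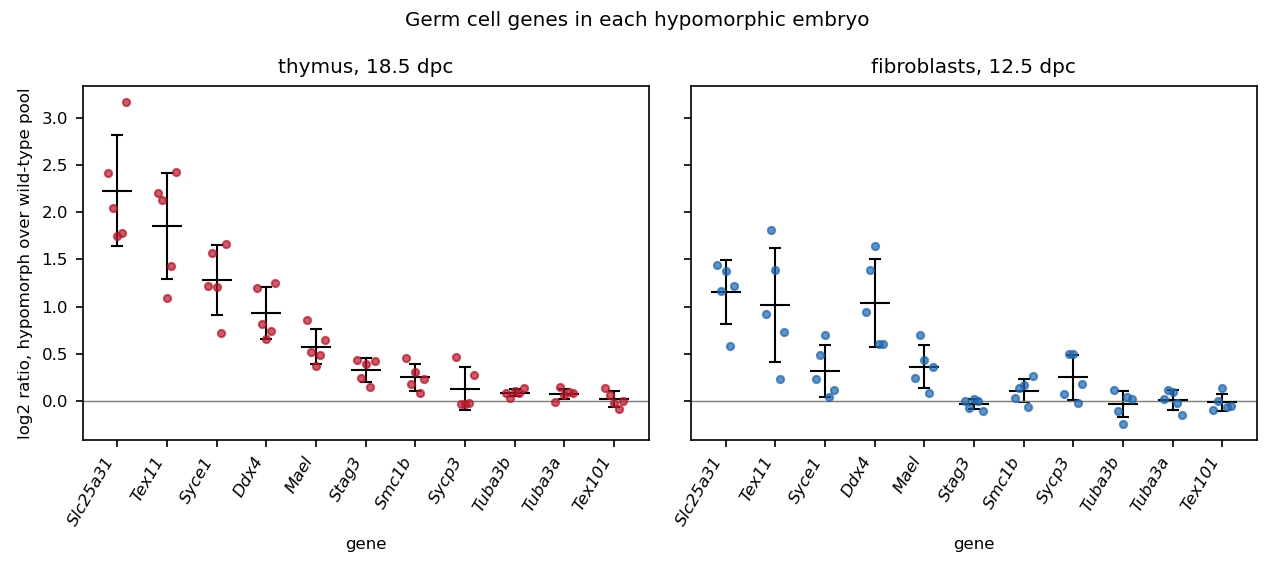
Log2 ratio, hypomorph over wild-type pool, of the 11 germ cell genes of the study's list. Points are the 5 embryos of each tissue, and bars are the mean ± SD. In thymus Slc25a31 lies at 2.23 and Tex11 at 1.85, and in fibroblasts at 1.16 and 1.02, while Tex101, Tuba3a and Tuba3b lie within 0.1 of 0 in both.

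Proliferation genes had the next smallest camera p in thymus after the study's germ cell genes. Of 31 measured cell cycle genes 28 lay above the pool, with a median of 0.14 (camera adjusted p = 3.17e-12), and 9 passed adjusted over the list alone and none over all genes. Bub1 (0.29 ± 0.16) and Bub1b (0.25 ± 0.15) of the spindle checkpoint, Cdc6 (0.26 ± 0.17) of replication licensing and the mitotic transcription factor Foxm1 (0.25 ± 0.19; SD, n = 5 each) were examples. Hypoxia and glycolysis genes shifted up too (median 0.05, camera adjusted p = 0.0105), with Pgk1 (0.28 ± 0.08), Bnip3 (0.25 ± 0.14) and Aldoa (0.19 ± 0.10) passing adjusted over the list of 18 alone. Erythroid genes did so with a median of 0.08 (camera adjusted p = 0.0132), where Fech, the last enzyme of heme synthesis, was the 1 of 16 to pass adjusted over the list alone (0.64 ± 0.33). With an estimated correlation the adjusted p was 0.193 for the cell cycle genes, 0.285 for hypoxia and glycolysis and 0.693 for the erythroid genes. The hypoxia and glycolysis shift was not called without embryo 2 (median 0.03, adjusted p = 0.0554) or 4 (0.04, 0.0534), and its median was 0.08 without embryo 3 or 5. Nor was it called without the members on the sex chromosomes (0.05, 0.0551). The erythroid shift was not called without embryo 1 (0.04, 0.0819) or without the arrays that lack the genotype in the label (0.03, 0.124), and in neither dye orientation alone (0.02, 0.737 with the hypomorph in Cy5 and 0.21, 0.285 in Cy3). In the arrays with the hypomorph in Cy3 alone the cell cycle median was -0.01 and the hypoxia and glycolysis median -0.01 (camera adjusted p = 0.950 and 0.488). With it in Cy5 alone they were 0.32 and 0.21. A dye effect of unequal size in the orientations was not tested for these lists and stays open.

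Several immune and stromal groups lay lower in thymus. The myeloid genes had a median of -0.07 (camera adjusted p = 4.35e-04), with Ltf, lactoferrin, at -0.23 ± 0.10. MHC class II and antigen presentation genes had a median of -0.05 (camera adjusted p = 0.00269), with H2-Oa (-0.41 ± 0.12) and H2-DMa (-0.24 ± 0.14). Fibroblast and matrix genes had a median of -0.04 (camera adjusted p = 0.00269). There S100a4 (-0.45 ± 0.14), Postn (-0.42 ± 0.25) and Sparc (-0.30 ± 0.18) lay lower while fibronectin, Fn1, lay higher at 0.36 ± 0.17. Thymocyte genes had a median of -0.06 (camera adjusted p = 0.00407), with Trat1 (-0.27 ± 0.09) and Cd3d (-0.21 ± 0.04), both parts of the T cell receptor complex. These 9 genes passed adjusted over their own list alone and none of them over all genes (SD, n = 5 each). With an estimated correlation the adjusted p was 0.478 for myeloid, 0.478 for MHC class II, 0.693 for fibroblast and matrix and 0.865 for thymocyte genes. The thymocyte median differed between embryos, at -0.26, 0.11, -0.20, 0.08 and -0.20 in embryos 1 to 5. The lymphocyte recombination genes Rag1 (-0.86, 0.70, -0.68, 0.74 and -0.53) and Dntt (-1.82, 0.62, -1.68, 0.20 and -1.29) had the same pattern of signs. The thymocyte shift was not called without embryo 1 (-0.02, adjusted p = 0.299), 3 (-0.03, 0.241) or 5 (-0.01, 0.149), and its median was -0.12 without embryo 2 and -0.11 without embryo 4. The fibroblast and matrix shift was not called without embryo 3 (-0.04, 0.130), and its median was -0.06 without embryo 1 or 4. The MHC class II median was -0.03 without embryo 1 or 4 and -0.10 without embryo 3, and the myeloid median -0.03 without embryo 2 and -0.04 without embryo 4. In the arrays with the hypomorph in Cy5 alone the thymocyte median was 0.03, and the tests of the MHC class II and the fibroblast and matrix list turned upward as well. The myeloid median there was 0.01 (adjusted p = 0.873).

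The remaining 18 lists had camera adjusted p from 0.0546 upward in thymus. They were ribosomal proteins (median -0.05), immediate early genes (-0.05), p53 targets (0.05), neural genes (-0.03), E2F6 and its Polycomb complex (0.04), DNA methylation machinery (0.02), interferon-stimulated genes (-0.03), imprinted genes (0.02), B and natural killer cell genes (0.04), the Rhox cluster (-0.03), adipose (0.01), cartilage and bone (0.01), endothelial (0.00), skeletal muscle (-0.01), cholesterol synthesis (0.03), HOX genes (0.01), smooth muscle (0.02) and thymic epithelium (0.00) besides the other germ cell genes. The median and the test differed in sign for adipose, cartilage and bone, smooth muscle and thymic epithelium, whose means were -0.05, -0.03, -0.06 and -0.01. Single members of these lists passed adjusted over their list alone. They were Uhrf1 (0.26 ± 0.11), the hemimethylation reader, Ccng1 (0.32 ± 0.06), Nes (0.18 ± 0.10), Adipoq (-0.74 ± 0.47), Lpl (-0.31 ± 0.15), Sox2 (-0.37 ± 0.24, but 3.53 in the arrays with the hypomorph in Cy3 alone), Stmn2 (-0.16 ± 0.09), Mbp, Spp1 (-0.38 ± 0.19) and Insig1 (-0.32 ± 0.16; SD, n = 5 each).

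The second comparison asked the same of embryonic fibroblasts. No named gene passed in the centred embryo values with all arrays as labelled, and the largest values were decreases. Ifi202b, an interferon-inducible gene whose expression differs between mouse strains, was at -4.07 ± 0.79 (SD, n = 5; 16.8-fold lower; limma adjusted p = 0.0903), and Cd44, the hyaluronan receptor, at -1.95 ± 0.72 (adjusted p = 0.128). Sfrp2, a secreted Wnt antagonist, was the highest at 1.94 ± 0.88 (SD, n = 5; adjusted p = 0.130). Slc25a31 was at 1.16 ± 0.34, Ddx4 at 1.03 ± 0.46 and Tex11 at 1.02 ± 0.61. Each of these genes had the same sign in all 5 embryos.

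Of 22025 features in fibroblasts 1 passed, an unnamed probe at -0.87, while 3536 had an unadjusted p under 0.05, where chance gives 1101. Without array 4 of embryo 4, the array that ran opposite, 83 features passed, 19 higher and 64 lower. Slc25a31 (1.28), Tmem87a (0.92) and 8030474K03Rik (0.94) then rose and Ifi202b (-4.34), Cd44 (-2.07), Cap1 (-1.29), an actin-binding protein, and Swap70 (-1.04) fell (adjusted p from 0.00576 to 0.0417). The array was left out after it was seen to run opposite, in Ifi202b, Cd44 and Slc25a31 among others. Leaving it out narrows the spread of such genes, so these calls are not independent support. Without all 3 doubted arrays 7 passed, 3 higher and 4 lower. The values as deposited gave 8, 3 higher and 5 lower, with all arrays, and among them Ifi202b, Cap1 and F3 fell and Slc25a31, Tmem87a and 8030474K03Rik rose. Ifi202b also passed with arrays scaled to equal spread. A fit of single arrays called 2115 features, 1112 higher and 1003 lower, among them Ifi202b, Cd44, Sfrp2 and Slc25a31. That fit can count technical repeats in part as replicates. In the embryo values, leaving out an embryo gave 38 without embryo 4 and 0 without any other. The pool is 1 control sample here too.

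The other decreases with all arrays were Ppp3r1 (-1.37 ± 0.73), Thbs1 (-1.20 ± 0.78), Cap1 (-1.17 ± 0.34), Cttn (-1.09 ± 0.60), Tll1 (-1.04 ± 0.39), Plaur (-1.03 ± 0.59), Swap70 (-0.99 ± 0.40), F3 (-0.99 ± 0.22), Pdlim5 (-0.95 ± 0.57) and Cd59a (-0.92 ± 0.51). Cap1, Cttn and Pdlim5 act on the actin cytoskeleton, and F3 and Plaur are tissue factor and the urokinase receptor. The other increases were the limb homeobox gene Pitx1 (0.97 ± 0.56), Tlr2 (0.88 ± 0.48), 8030474K03Rik (0.86 ± 0.18), the mismatch repair gene Msh6 (0.83 ± 0.50), 3830403N18Rik (0.81 ± 0.35), Tmem87a (0.81 ± 0.22), Scand1 (0.80 ± 0.43) and Robo1 (0.75 ± 0.52; SD, n = 5 each). In the centred embryo values with all arrays none of these passed over all genes (adjusted p from 0.115 to 0.187), while the fit of single arrays called each of them except Pitx1 and Tlr2, which it did not test. As that fit can count technical repeats in part as replicates, its calls are not support beyond the 5 embryos.

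The germ cell genes of the study's list had a median of 0.25 in fibroblasts (camera adjusted p = 0.00264; adjusted p = 0.812 with an estimated correlation). Of 11 members 8 lay above the pool. None passed over all genes, and Slc25a31, Ddx4, Tex11 and Mael (0.36 ± 0.23) passed adjusted over the list alone. The others were Syce1 (0.31 ± 0.27), Sycp3 (0.25 ± 0.24), Smc1b (0.11 ± 0.12), Tuba3a (0.01 ± 0.11), Tex101 (-0.01 ± 0.09), Stag3 (-0.03 ± 0.05) and Tuba3b (-0.03 ± 0.14; SD, n = 5 each). Without the array that ran opposite 7 members passed adjusted over the list alone, and Slc25a31 over all genes. That array was left out after it was seen to run opposite, in Slc25a31 among others, so these passes are not independent support. In the arrays with the hypomorph in Cy5 alone the list was not called (median 0.20, adjusted p = 0.531). The array titles carry different prefixes, whose meaning is not given. Array 4 of embryo 1 has the prefix AYY, and its other arrays and those of embryos 4 and 5 have AYT. In embryo 2 array 3 has AYY and the others AYX. In embryo 3 the arrays with the hypomorph in Cy5 have AYX and those with it in Cy3 have AYY. Prefix and dye orientation cannot be told apart in embryo 3. Values for the prefix AYT rest on embryos 1, 4 and 5, and those for AYX or AYY on embryos 2 and 3. The list's median was 0.11 with AYT and 0.50 with AYX or AYY (camera adjusted p = 0.00999 and 0.00755). The list of other germ cell genes was not called in fibroblasts either (median 0.01, camera p = 0.0277 upward, adjusted p = 0.112), which does not show that it had no shift.

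Cell cycle genes shifted up in fibroblasts with a median of 0.25 (camera adjusted p = 2.81e-05), with 29 of 31 above the pool and none passing even over the list alone. Their median was 0.52, 0.30, -0.24, 0.07 and 0.65 in embryos 1 to 5, and 0.40 in arrays with the prefix AYT against 0.05 in those with AYX or AYY. Interferon-stimulated genes (median 0.09, camera adjusted p = 6.73e-04), ribosomal protein genes (0.08, 0.00551) and DNA methylation genes (0.08, 0.0449) shifted up as well. In the last list Mbd1 (0.49 ± 0.29), Cdca7 (0.36 ± 0.26), Zbtb24 (0.25 ± 0.16) and Tet2 (0.17 ± 0.09) were higher in all 5 embryos (SD, n = 5) and passed adjusted over the list alone, as did Zbtb33 as lower (-0.12 ± 0.06). Cdca7 and Zbtb24 are, like Dnmt3b, genes whose human counterparts are mutated in ICF syndrome. With an estimated correlation the adjusted p of these lists, cell cycle included, was 0.812. The ribosomal shift was not called without embryo 1 (0.05, adjusted p = 0.245) or without the 3 doubted arrays (0.09), and its median was 0.12 without embryo 5. The DNA methylation shift was not called without embryo 1 (0.09, 0.0802), 2 (0.07, 0.0671) or 5 (0.04, 0.210). In the arrays of 1 dye orientation alone none of these lists was called, except cell cycle with the hypomorph in Cy5. With the prefix AYT the interferon (0.04, 0.0548) and ribosomal shifts (0.01, 0.738) were not called, and with AYX or AYY those of cell cycle (0.05, 0.987) and DNA methylation (0.08, 0.506) were not.

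**Figure D3:**
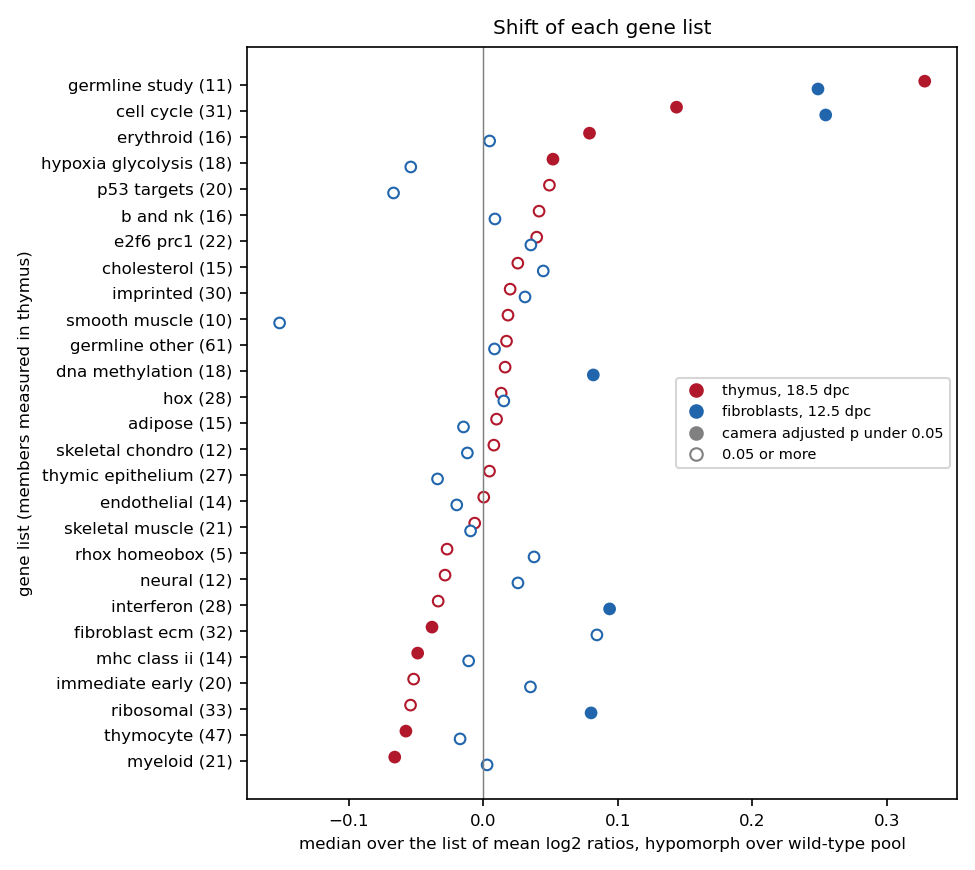
Median over each list of the mean log2 ratios, hypomorph over wild-type pool, in thymus and fibroblasts. Filled points had a camera adjusted p under 0.05 with a preset correlation. The study's germ cell list lies at 0.33 and 0.25 and the cell cycle list at 0.14 and 0.25.

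The remaining 21 lists had camera adjusted p from 0.112 upward in fibroblasts. They were smooth muscle (median -0.15), hypoxia and glycolysis (-0.05), p53 targets (-0.07), immediate early (0.04), imprinted (0.03), thymocyte (-0.02), B and natural killer cell (0.01), E2F6 and its Polycomb complex (0.04), thymic epithelium (-0.03), cholesterol synthesis (0.04), the Rhox cluster (0.04), fibroblast and matrix (0.08), endothelial (-0.02), skeletal muscle (-0.01), MHC class II (-0.01), HOX (0.02), adipose (-0.01), erythroid (0.00), myeloid (0.00), neural (0.03) and cartilage and bone (-0.01) besides the other germ cell genes. The median, mean and test did not share 1 sign for MHC class II, adipose, endothelial, erythroid, myeloid, neural and cartilage and bone. Of the p53 targets, 4 were lower in all 5 embryos and passed adjusted over the list alone: Pmaip1 (-0.68 ± 0.47), Ccng1 (-0.68 ± 0.31), Plk2 (-0.59 ± 0.15) and Eda2r (-0.57 ± 0.24). Ldha (-0.45 ± 0.24) and Vegfa (-0.32 ± 0.13) of the hypoxia list, the imprinted RNA Rian (-0.82 ± 0.28), Cd44, Notch1 (0.59 ± 0.20), Ebf1 (0.47 ± 0.19) and Elavl4 (-0.52 ± 0.22; SD, n = 5 each) passed over their own lists alone too. None of these passed over all genes.

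The third comparison tested whether the ratio of hypomorph over pool differed between thymus and fibroblasts. Ifi202b differed by 4.41 ± 0.46 (SE, n = 5 per tissue; limma adjusted p = 0.00864), from 0.34 in thymus to -4.07 in fibroblasts, and Cd44 by 1.97 ± 0.28 (adjusted p = 0.0298), from 0.02 to -1.95. Sfrp2 differed the other way by -2.44 ± 0.37 (adjusted p = 0.0324), from -0.50 in thymus to 1.94 in fibroblasts. Ccng1, a p53 target, and Fech lay higher in thymus (0.32 and 0.64) and lower in fibroblasts (-0.68 and -0.35), with differences of 1.00 ± 0.13 and 0.99 ± 0.15. Mfap4, a matrix protein of elastic fibres, and Mrpl55 had the opposite signs (-0.50 and -0.32 in thymus, 0.67 and 0.38 in fibroblasts).

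In total 89 of 21850 features passed for the difference, 51 higher in thymus and 38 lower. Other named genes higher in thymus than in fibroblasts were Cap1 (1.12), Chp1 (1.09), Tll1 (1.04) and Ripk2 (0.99). Those lower in thymus were H2bu2 (-1.10), Fxyd1 (-0.76), Pcp4l1 (-0.73), Epha7 (-0.69) and Ly6d (-0.68). Without array 4 of fibroblast embryo 4 the count was 291, 165 higher and 126 lower. Leaving out 1 embryo moved it from 1 (without thymus embryo 5) to 374 (without fibroblast embryo 4), and the values as deposited gave 17. Each pool's own deviation is part of these differences, and age and tissue changed together.

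**Figure D4:**
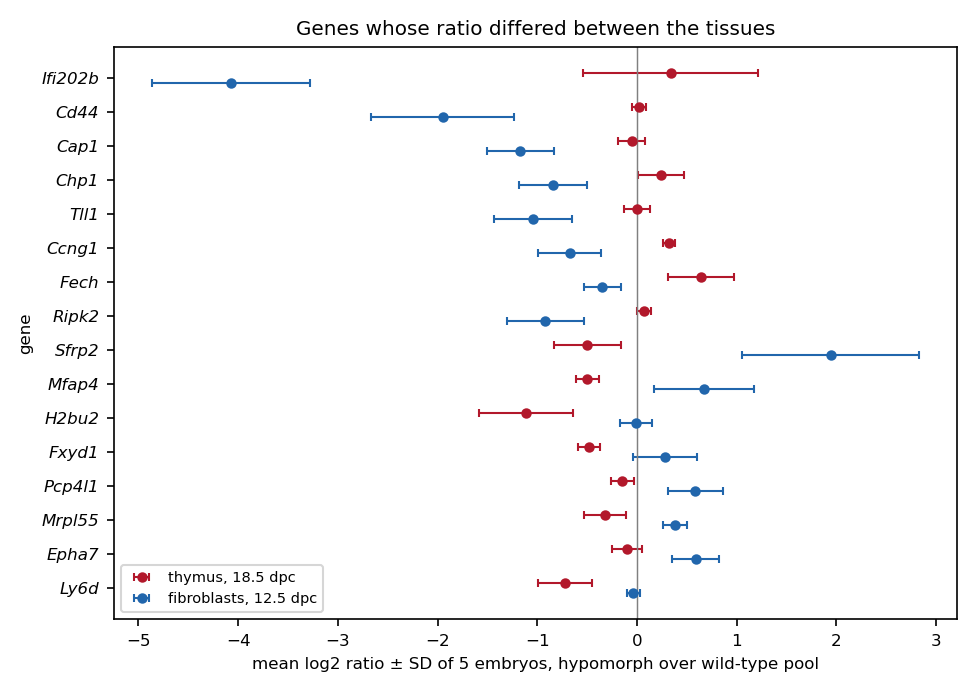
Mean log2 ratio ± SD of 5 embryos, hypomorph over wild-type pool, in thymus and fibroblasts, for the 8 genes with the largest difference on each side. Ifi202b lies at 0.34 in thymus and at -4.07 in fibroblasts, and Sfrp2 at -0.50 and 1.94.

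None of the germ cell genes of the study's list passed the test of the difference over all genes. Slc25a31 differed by 1.07 (adjusted p = 0.0992), Syce1 by 0.96 (0.0533), Tex11 by 0.84 (0.252) and Stag3 by 0.36 (0.0533), all higher in thymus, and Ddx4 by -0.10 (0.851). As a list they lay higher in thymus by a median of 0.14 (camera adjusted p = 0.00350), as did hypoxia and glycolysis genes (0.15, 0.0274) and p53 targets (0.11, 0.0338). Ribosomal protein (-0.18, 8.16e-04), interferon-stimulated (-0.10, 0.00647) and myeloid genes (-0.07, 0.0338) lay lower in thymus than in fibroblasts. With an estimated correlation the adjusted p was 0.778 for the ribosomal list and 0.624 for the 5 others. Across 21850 features the mean ratios of the tissues correlated at r = -0.0978, where genes are not independent replicates.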

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

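The tests of explanations in this part and in the other observations were all chosen after the results they bear on had been seen.

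Array 4 of fibroblast embryo 4 ran opposite to the other fibroblast arrays, with Ifi202b at 0.76, Cd44 at 1.00 and Sfrp2 at -2.41. Dyes recorded the other way round stay open over all probes, because the array was singled out for its sign, and turning it only mirrors its mean correlation with the other 3 arrays of its embryo from -0.375 to 0.375. The Y-linked gene Eif2s3y argues against them for the same embryo, because turning the sign puts it at -3.16, outside the -0.51 to 0.35 of the other 3 arrays, so a turned sign alone does not make this array match its embryo. Array 4 of embryo 1 (r = 0.930 with array 3 of embryo 2) and array 2 of the same embryo (Eif2s3y at 0.28 against -2.08 and -2.21) may carry the label of another sample, which stays open because the same values singled them out. Array 4 of embryo 1 and array 3 of embryo 2 also share the title prefix AYY, while the other arrays of embryo 1 have AYT. Whether the prefix bears on their correlation was not tested. No biological explanation was tested, and no label was changed.

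Germ cell genes of the study's list lay above the pool in both tissues, with 7 passing in thymus and 4 in fibroblasts adjusted over the list alone. A dye effect of equal size in both orientations cancels in the embryo values, where the list's median was 0.328 in thymus and 0.249 in fibroblasts, which argues against it as the whole cause. One of unequal size would still turn sign with the orientation. The thymus medians of 0.346 (Cy5) and 0.681 (Cy3), called in both and above 0 in all 5 embryos, argue against it there for the list's median. In each orientation 9 of 11 members lay above 0. The study chose the list on these samples, so a rise in both orientations is not independent support. Such a dye effect stays open in fibroblasts, where the Cy5 median of 0.198 (SD 0.203 between embryos) was not called and only 3 of 5 embryos lay above 0. Germ cells within the samples stay open: 18 primordial germ cell markers, written after the pattern was seen and 12 of them also in the list of other germ cell genes, had a median of 0.0371 in thymus against 0.93 for the 7 that passed, and of -0.0297 in fibroblasts against 1.03 for the 4 that passed, but only 1 and 2 of them moved by over 0.5 in any embryo, so the probes may not respond. A chance deviation of the wild-type pools stays open too: outside the chromosome that carries Dnmt3b 15 genes were higher in both tissues at an unadjusted p under 0.01, where independent lists give 2.93 (Fisher's exact p = 2.36e-07), but 16 were lower in thymus and higher in fibroblasts, where they give 6.61 (p = 0.00105), so independence does not hold as a baseline, and lower DNA methylation of these genes, which the genotype would predict, was not measured here.

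Reversing the signs of embryos tests the counts of calls against chance. The 5 embryos of a tissue give 16 sign patterns, too few for a share under 0.05. In thymus 2 patterns gave at least as many calls, the real one with 8 and another with 1493, and in fibroblasts 1 pattern did, the real one with 1, against 0 in the highest other. For the difference between tissues 1 of 100 splits of the 10 embryos gave as many calls, the real one with 89, against 0 in the highest other. The count thus goes with the tissues, but each tissue has its own pool and age, which every other split mixes. A deviation of a pool, shared by the 5 embryos of its tissue, is not tested by these splits. The count was 1 without thymus embryo 5 or with the replicate block, and 0 with the hypomorph in Cy5 only (limma, 2199 at an unadjusted p under 0.05).

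The thymus pattern with 1493 calls turned embryos 2 and 4 against the others and points to a structure of the samples. Across genes embryos 2 and 4 correlated at r = 0.523 and embryos 1, 3 and 5 between 0.403 and 0.436, while pairs across the 2 sets lay between -0.319 and 0.00109. Thymus Scgb3a2, a secretoglobin of the airways chosen after its values were seen, was at 0.11, -2.94, -0.07, -3.26 and 0.28 in embryos 1 to 5. The gap between the array medians of the dye orientations, as deposited, was 0.03, 1.79, 1.11, 1.83 and -0.25 in the same embryos. All thymus arrays share 1 title prefix, so no batch in the labels separates them. Of the sex-linked genes, Kdm5d was at -1.79, 0.60, -0.27, 0.54 and -0.19 in embryos 1 to 5, and Eif2s3y was also above 0 in embryos 2 and 4 only. Xist was below 0 in these 2 alone (-0.27 and -0.21, others 0.01 to 0.68), while Uty was above 0 in embryo 3 as well (0.012). Whether sex goes with the structure was not tested.

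In 10 of 139 groups of 5 embryos 1 embryo stood apart from the other 4, where chance gives about 6.95. In thymus these were Myof in embryo 4 (0.59, others 0.69 to 0.72), Lpl in embryo 2 (-0.057, others -0.42 to -0.33), Foxm1 in embryo 2 (0.58, others 0.09 to 0.22), Ifi202b in embryo 4 (-1.17, others 0.52 to 1.15) and Epha7 in embryo 5 (0.16, others -0.23 to -0.13). The Y-linked genes Eif2s3y (-3.43) and Uty (-0.55) stood apart in thymus embryo 1. In fibroblasts these were Ppp3r1 in embryo 4 (-0.081, others -1.84 to -1.59), Rian in embryo 4 (-0.32, others -0.99 to -0.89) and Ebf1 in embryo 3 (0.81, others 0.34 to 0.46). Embryo 4 includes the array that ran opposite.

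The ratio of hypomorph over pool differed between thymus and fibroblasts, by the limma test of the difference, for 23 of the named genes. Each tissue has 1 pool, whose own deviation is part of these differences. Higher in thymus were Ifi202b (4.41), Cd44 (1.97), Cap1 (1.12), Chp1 (1.09), Tll1 (1.04), Ccng1 (1.00), Fech (0.99), Ripk2 (0.99), F3 (0.99), Plk2 (0.75), Ldha (0.62) and Vegfa (0.45). Lower in thymus were H2-Oa (-0.44), Ebf1 (-0.53), Krt10 (-0.63), Ly6d (-0.68), Epha7 (-0.69), Mrpl55 (-0.71), Pcp4l1 (-0.73), Fxyd1 (-0.76), H2bu2 (-1.10), Mfap4 (-1.17) and Sfrp2 (-2.44). By camera the median difference was 0.14 for the study's germ cell list, 0.15 for hypoxia and glycolysis and 0.11 for p53 targets, and -0.18 for ribosomal, -0.097 for interferon-stimulated and -0.065 for myeloid genes, none of them called with an estimated correlation.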

How the results depend on the processing

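Centred print blocks and the fibroblasts without doubted arrays were chosen after seeing the data. The values as deposited had been planned as the main setting. Counts of calls moved with most choices, and the arrays give no signal over background, so what depth limits is unknown. The causes were not tested, except that 1 dye orientation alone leaves the dye effect in the ratio, which the fit of single arrays called for 57.8% of features in thymus and 58.9% in fibroblasts. With the hypomorph in Cy5 only, 4884 features were called in thymus, 6313 in fibroblasts and 0 for the difference (2199 at an unadjusted p under 0.05), and with it in Cy3 only 5251, 8157 and 285. Values as deposited gave 1 (higher), 8 (3 higher, 5 lower) and 17 (9 and 8), print blocks centred 4 in thymus (3 and 1), and equal median absolute deviations 13 (9 and 4) in thymus and 2 (both lower) in fibroblasts, with 39 higher and 23 lower for the difference. Features with 3 or more embryos gave 4 and 0 (3538 at an unadjusted p under 0.05), embryo weights 255 in thymus and 788 for the difference, and the fit of single arrays 405 (132 and 273), 2115 (1112 and 1003) and 1573 (679 and 894). Without the array that ran opposite the counts were 83 in fibroblasts and 291 for the difference, and without the 3 doubted arrays 7 in fibroblasts. Fibroblast arrays with the prefix AYT gave 0 and those with AYX or AYY 0, with 2062 and 6657 at an unadjusted p under 0.05. Leaving out an embryo gave 0 to 4 in thymus, 0 to 38 in fibroblasts and 1 to 374 for the difference. In thymus the count was 0 without embryo 1, 3 or 5 (1105, 1630 and 1135 at an unadjusted p under 0.05), and in fibroblasts 0 without embryo 1, 2, 3 or 5 (2203, 2005, 2620 and 4197). The other alternatives kept the counts within 1.5 times.

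The embryo number is shared between tissues by name only: same-numbered embryos correlated at 0.0354, 0.0152, -0.0358, 0.0886 and 0.00523 across genes, and only embryo 4 correlated best with its own number. With the replicate block the difference had 1 call.

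Of the lists, 8 in thymus and 5 in fibroblasts were called. Arrays with the hypomorph in Cy5 only gave 4 and 1, and in Cy3 only 3 in fibroblasts. An estimated correlation gave 0 and 0, and fry 3 and 0. Leaving out an embryo gave 3 to 6 in fibroblasts (3 without embryo 1).

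Of 2505 values of the 124 gene values and 13 list medians under alternatives, 1916 kept direction and side of the threshold, 272 fell out of it, 264 came into it and 53 reversed, 28 of these with 1 dye orientation only. Thymus with Cy5 only gave, as list medians or tests of opposite sign, 0.029 for thymocyte, -0.0044 for MHC class II and -0.027 for fibroblast and matrix genes, and as genes 0.025 for Cd3d, 0.098 for Stmn2, -0.055 for Dnmt1, -0.42 for Sycp3 and -0.62 for Tex101. Thymus with Cy3 only gave -0.013 for cell cycle and -0.013 for hypoxia and glycolysis, 3.53 for Sox2, -0.069 for Nes, -0.015 for Bub1, -0.016 for Bub1b, -0.083 for Pgk1, -0.019 for Dnmt3a, -0.13 for Dnmt3l, -0.094 for Tuba3a and -0.059 for Tuba3b. In thymus separate probes gave -0.11 for Dnmt1 and embryo weights -0.0018 for Dnmt3a, and leaving out an embryo -0.017 to 0.23 for Dnmt3l and -0.011 to 0.045 for Tex101. Fibroblasts with Cy5 only gave -0.029 for Dnmt3l, -0.22 for Smc1b, 0.048 for Stag3, -0.24 for Sycp3 and 0.054 for Tuba3b, and with Cy3 only -0.075 for Tet2, 0.18 for Dnmt1, 0.51 for Tex101 and -0.18 for Tuba3a. In fibroblasts values as deposited gave 0.012 for Dnmt1 and 0.0081 for Tex101, print blocks 0.0089, 0.0075 and -0.0081 for Dnmt1, Tex101 and Tuba3a, and separate probes 0.0037 for Dnmt1. Without the 3 doubted arrays Tex101 was at 0.010, Tuba3a at -0.0067 and Tuba3b at 0.017. The prefix AYT gave -0.087 for Tuba3a and 0.11 for Tuba3b, and AYX or AYY 0.068 for Tex101 and 0.051 for the cell cycle list, whose test turned. Leaving out a fibroblast embryo gave -0.051 to 0.022 for Dnmt1, -0.018 to 0.033 for Dnmt3l, -0.054 to 0.0060 for Tex101, -0.014 to 0.052 for Tuba3a and -0.072 to 0.018 for Tuba3b.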

Other observations

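Outside the study's list 16 named genes were higher in both tissues at an unadjusted p under 0.01, where independent lists give 3.26 (Fisher's exact p = 1.68e-07). With the chromosome of Dnmt3b left out as well 11 remained, where independent lists give 2.74 (Fisher's exact p = 9.50e-05). Part of this overlap thus lies on the chromosome of the altered gene, with Ahcy among the neighbours of Dnmt3b. Over all named genes those of opposite direction exceeded their expectation too (29 against 11.8). The genes are named here after their values were seen. Tex12, a component of the synaptonemal complex, was at 0.51 in thymus and 0.25 in fibroblasts, and the X-linked lymphocyte-regulated genes Xlr (0.44 and 0.28) and Xlr3a (0.22 and 0.28) lay with it. Gpat2 was at 1.42 and 0.74, Taf7l at 1.25 and 0.46, and 8030474K03Rik at 1.09 and 0.86. In the same set were Bub1b at 0.25 and 0.43, the separase gene Espl1 at 0.19 and 0.40, Oip5 at 0.33 and 0.71, and the histone gene H2ax at 0.20 and 0.73. So was Ahcy (0.27 and 0.53), which clears the S-adenosylhomocysteine left by methyl transfer. In the centred embryo values with all arrays Gpat2 and Taf7l passed over all genes in thymus and none of the 16 in fibroblasts, where 8030474K03Rik and Tmem87a passed in the values as deposited. Genes lower in both tissues were not more frequent than chance allows (13, against 9.57 of independent lists, Fisher's exact p = 0.245). Among them S100a4 was at -0.45 and -0.43 and Gfap at -0.34 and -0.60.

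Without the fibroblast array that ran opposite, further genes fell by the limma test, named here after their values were seen. The prostaglandin synthesis genes Ptgs2 (-0.66) and Pla2g4a (-0.44), the matrix crosslinking gene Loxl4 (-1.02), the imprinted RNA Rian (-0.89), the p53 target Plk2 (-0.64) and the amyloid precursor gene App (-0.79) were among them. Notch1 (0.65), the Wnt effector gene Tcf7l2 (0.48), the replication kinase gene Cdc7 (0.46) and H2ax (0.80) rose. Adjusted p lay between 0.00576 and 0.0496 for the named genes called there. The array was left out because it ran opposite, which narrows the spread of genes that ran opposite on it. These calls are therefore not independent support.

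A hypothesis, whose tests were chosen after the values had been seen, was that genes near Dnmt3b differ more often, as they could where the mutant allele brings the flanking haplotype of 1 parental strain. Of the 400 nearest measured genes, by gene order in the reference table (GRCm38.p6), 3.75% had an unadjusted p under 0.01 in thymus, against 2.35% on the rest of that chromosome, and 6.75% against 6.07% in fibroblasts. Rotations of the gene order gave as many in thymus at p = 0.0891 and in fibroblasts at p = 0.178 (permutation tests), so chance order is not excluded. A haplotype with few differing genes cannot be told apart from none with these shares. Of the named genes Scand1 lies among these neighbours. Of 4 neighbours under 0.01 in both tissues 3 had the same sign, Ahcy, Dynlrb1 and Rab5if, and Cst3 had opposite signs. Over all named genes 20 were higher and 13 lower in both tissues at that p, where independent lists give 3.45 and 9.57. Without the chromosome of Dnmt3b these were 15 and 9 (2.93 and 8.71). Genes higher in thymus and lower in fibroblasts went from 9 (4.54) to 8 (3.86), and the reverse from 20 (7.28) to 16 (6.61). Whether that chromosome holds more than its part of the overlap was not tested.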
